A study of Homo sapiens with 10 samples.

How the data were processed

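The deposited counts per gene were used as the authors gave them. Per the submitters' processing notes, reads were aligned to hg19 with TopHat2 2.0.14 and counted with featureCounts 1.4.6 of the Subread package. Libraries came from an unstranded kit for polyadenylated RNA, and the counting settings for strand and for reads with several matches were not given. Values of antisense and overlapping genes and of close paralogs are therefore uncertain. The table held 25370 genes, among them 28 symbols turned into dates, 4 repeated symbols, 270 genes sharing exact exons and 326 listed on several chromosomes. The design text speaks of 15 samples in 3 independent experiments, and the 10 libraries here are 2 per group. The clone numbers in the sample descriptions differ from the library names, and the library names are used here. No library duplicated another. The labels do not say how cultures were separated, so p-values measure the spread between these libraries.

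Genes were kept by the expression filter of edgeR, which left 16490. TMM factors and quasi-likelihood tests of edgeR 4.0.16 were used with a mean per group, 5 residual degrees of freedom and Benjamini-Hochberg adjustment over all tested genes, and a gene passed at an adjusted p under 0.05. The comparisons were the mean of the 4 clones against parental, each clone against parental, each clone against the mean of the other 3, and all differences among clones. Genes changed the same way in all 4 clones passed in each with the same sign. CPM values are means over libraries, ± is the SD, and log2 fold changes carry the SE of the fit. For a gene with 0 reads in a group the fold is a bound at 3 counts over the group, and for 1 to 3 reads a ratio with its 95% counting interval.

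The 37 gene lists covered homologous recombination, end joining and end protection, PARP and single-strand break repair, fork protection and checkpoint, Fanconi anemia, drug efflux, translation termination and readthrough, nonsense-mediated decay factors and the transcripts it degrades, cytosolic ribosomal proteins, tRNA synthetases, ATF4 and integrated stress, endoplasmic reticulum unfolded protein, p53 targets, mitosis, DNA replication, interferon response, antigen presentation, NF-kB and inflammation, mesenchymal, epithelial, serous ovarian lineage, estrogen response, Wnt targets, cholesterol synthesis, NRF2 antioxidant, hypoxia and glycolysis, respiratory chain, NAD metabolism, stemness and aldehyde dehydrogenase, apoptosis regulators, cancer-testis, markers of fibroblasts, leukocytes, endothelium and mesothelium, and replication-dependent histones. They were written from general knowledge. Of 747 entries 745 were matched, 49 of them by an older symbol, and 686 were tested. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and as alternatives with an estimated correlation and with fry.

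The comparisons, the lists, the other settings to be run and the rule for naming genes were fixed before the data were examined. The rule named BRCA2, BRCA1, PARP1, PARP2, PARG, TP53BP1, MAD2L2, SLFN11, ABCB1, ABCG2, ETF1, GSPT1, UPF1 and SMG1 in any case, and some genes that fell under the rule are not reported here. It further named the 12 largest rises and falls with at least 5 CPM in the higher group that passed in the mean and, with the same sign, in each clone, the 5 largest rises and falls that set a clone apart, and up to 4 members of each list with the smallest adjusted p. Symbols of unnamed transcripts and genes of the sex chromosomes that tell sex were left out.

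Whether libraries with the same replicate number deviated together was checked over the 10 group pairs. The correlations of the deviations were 0.28 to 0.731, above the set threshold of 0.1, and a fit with the replicate number as a block (4 residual degrees of freedom) was run beside every comparison. The biological coefficient of variation was 0.368 without and 0.235 with the block. Alternatives also covered DESeq2 1.42.0 (size factors and Wald test), limma-voom, no filter, each library left out, only the compared groups and the clone as the unit. A length correction, alone and with the block, was chosen after seeing the data. The fit was tested on simulated data with 50 genes changed at each size and no replicate effect. In the mean comparison 10%, 88%, 98% and 100% of genes changed 2-fold, 4-fold, 8-fold and 16-fold were recovered, with 11 false among 159 calls. In ABTr1 against parental 0%, 40%, 90% and 98% were recovered. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.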

Results

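PEO1 is an established cell line grown from a high grade serous ovarian carcinoma and is deficient in BRCA2, a protein of the repair of broken DNA by homologous recombination. Cells with this defect are killed by inhibitors of PARP1, and the series compared parental PEO1 with 4 clones that had become resistant to the PARP inhibitor veliparib. The clones, called ABTr1, ABTr2, ABTr3 and ABTr4, had been kept in 40 µM veliparib for 6 months and were grown without the drug for 4 to 5 days before RNA was taken. Polyadenylated RNA was sequenced and reads were counted per gene. The 10 libraries analysed here were 2 of parental PEO1 and 2 of each clone, numbered replicate 1 and replicate 2. Total counts ran from 20640602 (ABTr2 replicate 2) to 55488566 (ABTr2 replicate 1), and replicate 1 was the deeper library in each of the 5 groups.

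The parental libraries stood apart from the clone libraries. Over the tested genes, Pearson's r of log2 CPM across genes was 0.949 to 0.972 between libraries of the same group, 0.929 to 0.984 between libraries of different clones and 0.883 to 0.939 between a parental and a clone library. Genes are not independent replicates, so these r values describe the libraries only. The principal component with the most variance (69.5%) separated parental cells from all 4 clones, and the next component (15.3%) ordered the libraries within each group by replicate number. Libraries with the same replicate number deviated together, so values from a fit with the replicate number as a block are given beside results that it moved.

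**Figure D1:**
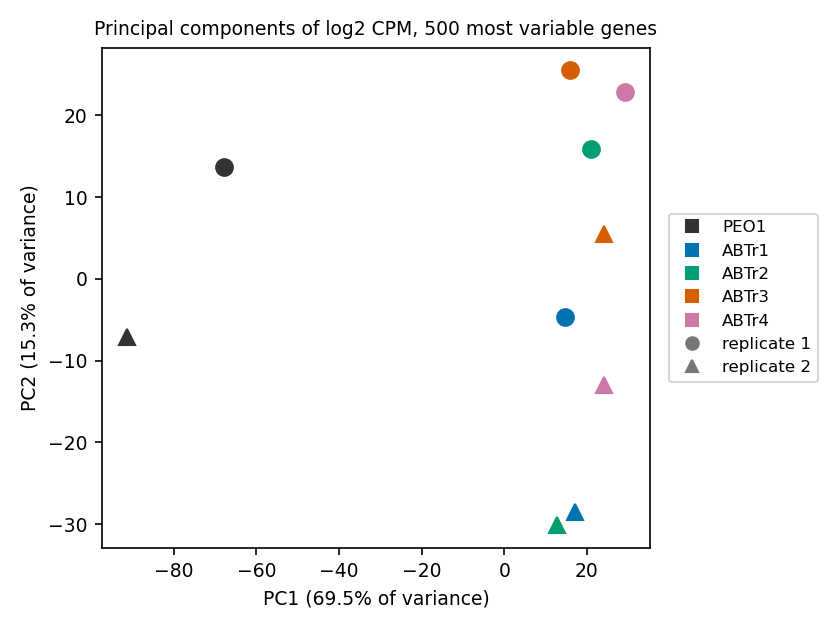
Each point is 1 library, placed by its scores on PC1 (69.5% of variance) and PC2 (15.3% of variance) of log2 CPM over the 500 most variable genes, with color for the group and shape for the replicate number. Both parental libraries lie at negative PC1 and the 8 clone libraries at positive PC1, and replicate 1 lies above replicate 2 in every group.

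Epithelial genes were lower in the resistant clones, and some mesenchymal and inflammatory genes were higher. The question of this comparison was which transcripts the resistant clones carry on average at another level than the cells they came from. E-cadherin (CDH1, chromosome 16), the adhesion protein of epithelial junctions, fell from 252 ± 149 CPM (SD, n = 2 libraries) in parental cells to 1.88 ± 2.47 CPM (SD, n = 4 clones), a log2 fold change of -8.19 (SE 0.70, edgeR adjusted p = 3.3e-04). The intermediate filament vimentin (VIM, chromosome 10), a mesenchymal protein, rose from 1.67 ± 1.32 to 147 ± 157 CPM, 60.6-fold (log2 fold change 5.92, SE 0.64, edgeR adjusted p = 8.6e-04). With 1 library left out the log2 fold change of VIM ran from 5.31 to 7.09. The estrogen receptor gene ESR1 (chromosome 6) fell from 109 ± 20.3 to 0.569 ± 0.387 CPM, and the cytokine gene IL1B (chromosome 2) rose from 0.226 ± 0.101 to 159 ± 71.7 CPM. Of 16490 genes tested, 2631 passed at an edgeR adjusted p under 0.05 in the mean of the 4 clones against parental, 1182 of them higher and 1449 lower in the clones. With the replicate block 5699 genes passed, 2690 higher and 3009 lower, and these included all 2631. DESeq2 called 4072 genes and limma-voom 2387. Without PEO1 replicate 2 the count was 918. Of the called genes, 1035 of the higher and 1048 of the lower differed by at least 2-fold.

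The 12 largest falls among genes that passed in the mean and, with the same sign, in each clone were in VGLL1, GRHL2, INHBB, ALDH3B2, RBBP8NL, FXYD3, SLC22A3, CEACAM6, IL1R2, MAL, TMPRSS4 and IGFBP5. VGLL1 (X chromosome), a cofactor of TEAD transcription factors, fell from 139 ± 21.6 CPM to 0.0313 ± 0.0319 CPM, a log2 fold change of -12.65 (SE 0.43, edgeR adjusted p = 1.2e-05). GRHL2 (chromosome 8), a transcription factor that maintains epithelial identity, fell from 121 ± 15.5 to 0.0533 ± 0.0454 CPM (log2 fold change -11.87, SE 0.62, edgeR adjusted p = 8.0e-05). RBBP8NL had 424 parental reads and 0 reads in the 8 clone libraries, at least 659-fold lower against a floor of 3 counts over the group. ALDH3B2, an aldehyde dehydrogenase gene, had 1 clone read against 865 parental reads, a ratio of 4034 with a 95% counting interval of 722 to 159530. IGFBP5, which encodes a binding protein of insulin-like growth factors, was at 333 and 9277 CPM in the parental libraries, and its log2 fold changes were -7.58, -8.67, -10.01 and -10.86 in ABTr1, ABTr2, ABTr3 and ABTr4. Its mean log2 fold change was -9.28 (SE 0.88) and was -5.43 without PEO1 replicate 2. CEACAM6, a cell surface adhesion gene, likewise had 3.99 and 122 CPM in parental cells, and its log2 fold change of -10.12 (SE 1.01) was -6.16 without PEO1 replicate 2. Every one of these 12 genes passed in all 17 alternative settings run for it.

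The 12 largest rises were in MMP2, IL1B, EEF1A2, IL13RA2, VAT1L, HCLS1, FLI1, ITGB3, MAOA, CSF2, WSCD1 and SPP1. MMP2 (chromosome 16), a gelatinase that degrades extracellular matrix, had 1 parental read against 4866 clone reads, a ratio of 1043 with a 95% counting interval of 187 to 41217. Its log2 fold change of 9.68 was 12.11 without PEO1 replicate 1, when the remaining parental library had 0 reads, and 9.06 without PEO1 replicate 2. EEF1A2 (chromosome 20), a translation elongation factor, rose from 0.164 ± 0.0133 to 89.7 ± 60.2 CPM (log2 fold change 8.73, SE 1.08, edgeR adjusted p = 0.0015). HCLS1 (chromosome 3), a substrate of kinases in blood cells, rose from 0.217 ± 0.131 to 43.3 ± 3.04 CPM (log2 fold change 7.70, SE 0.59, edgeR adjusted p = 1.9e-04). FLI1 (chromosome 11), an ETS family transcription factor, had 2 parental reads against 1920 clone reads, a ratio of 206 with a counting interval of 56.9 to 1701. Its log2 fold change of 7.52 was 6.27 without PEO1 replicate 1, and 10.96 without PEO1 replicate 2, when the remaining parental library had 0 reads. ITGB3, which encodes the integrin beta 3 chain, rose 127-fold to 48.1 ± 15.3 CPM, and MAOA, the monoamine oxidase A gene, rose 111-fold to 32.0 ± 14.9 CPM. The log2 fold change of MAOA, 6.80, ran from 6.39 to 7.51 with 1 library left out. IL13RA2, a decoy receptor for interleukin 13, had 3 parental reads against 8122 clone reads, a ratio of 580 with a counting interval of 199 to 2815. Its log2 fold change of 8.32 was 12.15 without PEO1 replicate 1 and 7.61 without PEO1 replicate 2, its edgeR adjusted p of 0.019 was 0.088 and 0.13, and it also missed the threshold with limma-voom. CSF2, the gene of a myeloid growth factor, had a log2 fold change of 6.76 (SE 1.00), which was 10.94 without PEO1 replicate 1, when the parental level rested on a library with 0 reads. These intervals and floors cover counting error only.

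All 23 tested members of the epithelial list fell in the clones, as they did when adjusted over the list alone (median log2 fold change -3.43, camera adjusted p = 6.3e-48). The adjusted p was 0.057 with an estimated correlation. Besides CDH1 and GRHL2, EPCAM, a surface glycoprotein of epithelial cells, fell from 543 ± 0.586 to 110 ± 36.4 CPM, and OVOL1, a transcription factor that opposes mesenchymal programs, fell from 8.66 ± 1.38 to 0.0601 ± 0.0597 CPM (edgeR adjusted p = 1.7e-04). Of the 20 tested mesenchymal genes, 8 rose and 0 fell, 10 rose when adjusted over the list alone, and 10 rose and 1 fell with the block (camera adjusted p = 8.9e-08, and adjusted p = 0.091 with an estimated correlation). The transcription factor genes ZEB1 and ZEB2, repressors of E-cadherin, rose 18.6-fold to 45.7 ± 3.14 CPM and 27.4-fold to 28.7 ± 5.94 CPM. N-cadherin (CDH2) rose 10.6-fold to 95.3 ± 17.7 CPM. VIM, ZEB1, ZEB2 and CDH2 passed in all 17 alternatives. Fibroblast markers stood low beside this change: ACTA2, at 8.92 CPM in the clones, was the most abundant of the 12 on that list, and DCN, LUM and COL3A1 had 0 reads in all 10 libraries.

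**Figure D2:**
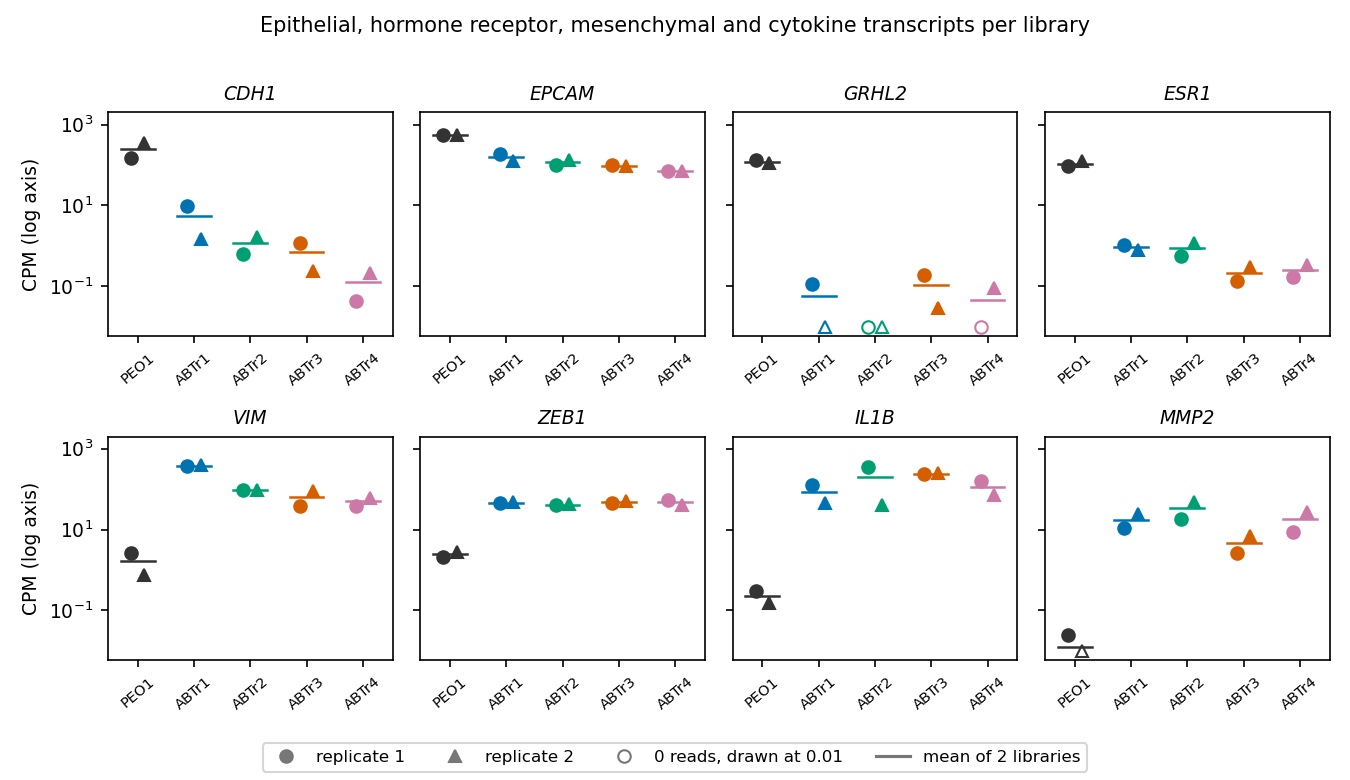
Level of 8 genes in each library in CPM on a log axis, by group, with circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2 libraries; open symbols are libraries with 0 reads, drawn at 0.01. CDH1, EPCAM, GRHL2 and ESR1 are lower in all 8 clone libraries than in both parental libraries, and VIM, ZEB1, IL1B and MMP2 are higher.

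Lineage and hormone genes changed in part. Of 12 tested serous ovarian lineage genes, 7 fell and 1 rose, over all genes and when adjusted over the list alone (camera adjusted p = 9.5e-09, and adjusted p = 0.057 with an estimated correlation). The secreted serine proteases KLK6 and KLK8 fell by 3.98 (SE 0.18) and 5.44 (SE 0.60) on the log2 scale, and MECOM, a zinc finger transcription factor gene often amplified in this cancer, rose 40.5-fold (log2 fold change 5.34, SE 0.59). PAX8, the lineage transcription factor of the fallopian tube, which was picked after its values were seen, was at 124 ± 44.5 CPM in parental cells and 137 ± 36.7 CPM in the clones (log2 fold change 0.10, SE 0.24, edgeR adjusted p = 0.81). That value was -0.23 without PEO1 replicate 2. Of 12 tested estrogen response genes, 4 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.24 with an estimated correlation). ESR1 led that list with a log2 fold change of -7.91 (SE 0.32, edgeR adjusted p = 1.2e-05), and MYB, a transcription factor gene, fell from 12.3 ± 0.461 to 1.36 ± 0.665 CPM. The edgeR adjusted p of MYB, 0.013, was 0.064 without PEO1 replicate 2.

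NF-kB and inflammation genes rose as a group. Of 17 tested, 8 rose and 1 fell, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.057 with an estimated correlation). With the replicate block 13 rose and 1 fell. IL1A, a cytokine of the same family as IL1B, rose from 0.616 ± 0.169 to 39.6 ± 18.5 CPM (log2 fold change 5.88, SE 0.56, edgeR adjusted p = 5.1e-04). The member that fell was LCN2, a secreted iron carrier protein of inflamed epithelia, at 73.4 and 550 CPM in the parental libraries and 4.11 ± 2.47 CPM in the clones (log2 fold change -6.42, SE 1.07, edgeR adjusted p = 0.0055). The LCN2 call ended without PEO1 replicate 2, and its log2 fold change ran from -7.49 to -4.34 with 1 library left out. The interferon response list did not pass (camera adjusted p = 0.88): of 34 tested, 3 rose and 3 fell, also when adjusted over the list alone, and 7 rose and 6 fell with the block. In single clones that list passed as higher in ABTr1 without ABTr1 replicate 1 and in ABTr2 without ABTr2 replicate 1. It passed as lower in ABTr3 without ABTr3 replicate 2. TREX1, a cytosolic DNA exonuclease, rose 2.34-fold to 6.48 ± 1.26 CPM, an edgeR adjusted p of 0.024 that reached 0.12 in other settings and passed the threshold neither without PEO1 replicate 1, PEO1 replicate 2 or ABTr1 replicate 1 nor with the clone as the unit. Of 14 antigen presentation genes, 1 fell, also when adjusted over the list alone, and 3 rose and 3 fell with the block (camera adjusted p = 0.82). That gene was ERAP1, an aminopeptidase that trims peptides for MHC class I (log2 fold change -1.71, SE 0.30, edgeR adjusted p = 0.0074). It stood at -0.84 with an edgeR adjusted p of 0.13 without PEO1 replicate 2.

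Some genes of amino acid supply, cholesterol synthesis and tRNA charging fell. Of 23 tested genes on the ATF4 and integrated stress list, 11 fell and 0 rose, and 14 fell when adjusted over the list alone (mean log2 fold change -1.63, camera adjusted p = 4.6e-06, and adjusted p = 0.58 with an estimated correlation). The heavy and light chains of the large neutral amino acid transporter, SLC3A2 and SLC7A5, fell by 2.22 (SE 0.37) and 2.78 (SE 0.44) on the log2 scale, and asparagine synthetase (ASNS) fell by 2.65 (SE 0.51). This group rested on PEO1 replicate 2. The list did not pass with fry (adjusted p = 0.10), and without that library it had a camera adjusted p of 0.17, and the log2 fold changes of SLC3A2, SLC7A5 and ASNS were -1.59, -2.19 and -0.87 with edgeR adjusted p of 0.090, 0.065 and 0.32. Of 17 tested cholesterol synthesis genes, 8 fell and 0 rose, 13 fell when adjusted over the list alone, and 13 fell with the block (camera adjusted p = 1.4e-05, and adjusted p = 0.58 with an estimated correlation). The lanosterol demethylase CYP51A1 fell from 229 ± 87.2 to 68.4 ± 19.7 CPM and passed in all 17 alternatives. Of 20 tested tRNA synthetase genes, 6 fell and 0 rose, 7 fell when adjusted over the list alone, and 11 fell with the block (camera adjusted p = 0.0093, and adjusted p = 0.58 with an estimated correlation). NARS, the asparaginyl-tRNA synthetase, fell by 1.39 (SE 0.20, edgeR adjusted p = 0.0027) on the log2 scale. Without PEO1 replicate 2 the tRNA synthetase list had a camera adjusted p of 0.12. The endoplasmic reticulum unfolded protein list did not pass (camera adjusted p = 0.81), with 0 of 16 genes called over all genes or over the list alone, and 1 higher and 3 lower with the block.

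Without the replicate block BRCA2 and most other repair transcripts did not pass, and with it BRCA2, PARP1 and MAD2L2 passed. BRCA2 (hg19 chromosome 13, 32889617 to 32973809) was at 12.4 ± 9.34 CPM (SD, n = 2 libraries) in parental cells and at 36.1 ± 11.6 CPM (SD, n = 4 clones) in the clones, a log2 fold change of 1.49 (SE 0.80, edgeR adjusted p = 0.25). With the replicate block it was 1.51 (SE 0.25, edgeR adjusted p = 0.0013), and each clone library stood above the parental library of its own number. BRCA2 also passed in each clone with the block (edgeR adjusted p = 8.8e-04 to 0.015). BRCA1, which acts in the same repair pathway, had a log2 fold change of -0.42 (SE 0.50, edgeR adjusted p = 0.62). PARP1, the target of veliparib, had one of 0.54 (SE 0.41, edgeR adjusted p = 0.42), which was 0.59 (SE 0.21, edgeR adjusted p = 0.0498) with the block. PARP2, PARG and TP53BP1, which encode another poly(ADP-ribose) polymerase, the enzyme that removes the polymer and a protein that limits end resection, had log2 fold changes of -0.28 (SE 0.21), 0.11 (SE 0.20) and 0.29 (SE 0.18). MAD2L2, a shieldin subunit that also limits resection, had one of 0.72 (SE 0.21, edgeR adjusted p = 0.054), with an edgeR adjusted p of 0.016 with the block and of 0.0089 to 0.32 over all alternatives; it also passed with DESeq2 and without PEO1 replicate 1. SLFN11, a helicase-like protein that blocks stalled forks, rose from 62.7 ± 0.121 to 119 ± 14.7 CPM (log2 fold change 0.91, SE 0.26, edgeR adjusted p = 0.044). With the block its log2 fold change was 0.88 (SE 0.17, edgeR adjusted p = 0.0027). The SLFN11 call ended without either PEO1, ABTr1 or ABTr3 library, without ABTr2 replicate 1, without ABTr4 replicate 1 and with the clone as the unit, with log2 fold changes of 0.82 to 0.98 and edgeR adjusted p of up to 0.20.

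**Figure D3:**
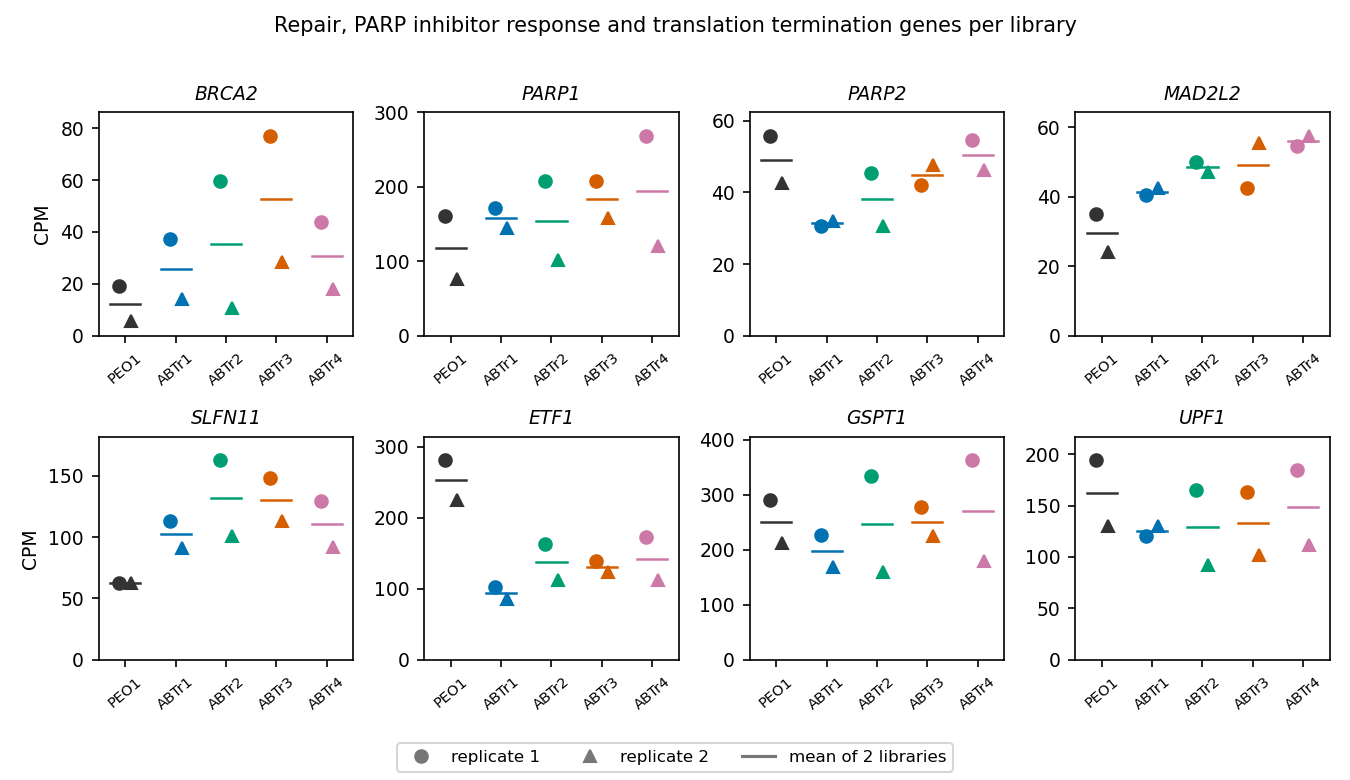
Level of 8 genes in each library in CPM, by group, with circles for replicate 1, triangles for replicate 2 and a line at the mean of the 2 libraries. BRCA2 is higher in each clone library than in the parental library with the same replicate number, ETF1 is lower in all 8 clone libraries than in both parental libraries, and PARP2, GSPT1 and UPF1 overlap between parental cells and clones.

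The DNA repair lists did not pass as groups in the mean of the 4 clones with all libraries kept. Of 25 tested homologous recombination genes, 2 fell and 0 rose, 1 fell when adjusted over the list alone, and 4 fell and 1 rose with the block (camera adjusted p = 0.82). The 2 were SHFM1, a small partner of BRCA2, with a log2 fold change of -0.76 (SE 0.16, edgeR adjusted p = 0.017), and RAD50, a subunit of the complex that senses broken ends, with one of -0.68 (SE 0.20, edgeR adjusted p = 0.049). The SHFM1 call ended without either parental library and with the clone as the unit (edgeR adjusted p up to 0.15). The RAD50 call ended without any one library other than PEO1 replicate 1 and in 3 other settings (edgeR adjusted p up to 0.37). Of 20 fork protection and checkpoint genes, 3 rose and 1 fell, 3 rose and 2 fell when adjusted over the list alone, and 5 rose and 5 fell with the block (camera adjusted p = 0.82). ETAA1, an activator of the ATR kinase, rose from 22.9 ± 3.14 to 48.3 ± 4.17 CPM (edgeR adjusted p = 0.013, and 0.11 without PEO1 replicate 2). Of 17 end joining and end protection genes, 17 PARP and single-strand break repair genes and 17 Fanconi anemia genes, 0 passed in each, also when adjusted over each list alone (camera adjusted p = 0.82, 0.80 and 0.82). With the block 1 rose and 1 fell, 2 rose and 3 fell, and 2 rose and 0 fell in these lists. In single clones the homologous recombination list passed as lower in ABTr1 without ABTr1 replicate 1 and in ABTr2 without ABTr2 replicate 1. The end joining list did so in ABTr1 without PEO1 replicate 2.

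Drug efflux genes were higher in part. Of 12 tested, 3 rose and 0 fell, 4 rose when adjusted over the list alone, and 6 rose with the block. The list missed the threshold (camera adjusted p = 0.082, 0.051 with the block), and the adjusted p = 0.58 with an estimated correlation (0.78 with the block). It passed with fry, which tests a list against no change and not against other genes (adjusted p = 0.032), without ABTr2 replicate 1 (camera adjusted p = 0.042) and without ABTr4 replicate 1 (camera adjusted p = 0.038). ABCA2, a lipid transporter gene, rose from 22.1 ± 3.60 to 47.2 ± 12.1 CPM (log2 fold change 1.06, SE 0.24, edgeR adjusted p = 0.019), and the edgeR adjusted p was 0.15 at the highest, which was without PEO1 replicate 2 or with the clone as the unit. ABCG2, an efflux pump that carries some PARP inhibitors, had a log2 fold change of 1.77 (SE 0.55, edgeR adjusted p = 0.061), and the edgeR adjusted p was 0.024 with the block and 0.0048 to 0.24 over all alternatives; it also passed with DESeq2 and without ABTr2 replicate 1. ABCB1 (hg19 chromosome 7, 87133179 to 87342639), the gene of P-glycoprotein, had only 18 parental reads, and its estimates differed in sign between clones. It had 0.293 ± 0.133 CPM in parental cells and 1.13, 1.44 and 0.734 CPM in ABTr1, ABTr2 and ABTr3, but 0 reads in both ABTr4 libraries, at least 7.16-fold lower than parental against a floor of 3 counts over the group (edgeR adjusted p = 0.020, up to 0.097 without PEO1 replicate 2 or either ABTr4 library). In ABTr1, ABTr2 and ABTr3 its edgeR adjusted p was 0.10, 0.080 and 0.26, and 0.045, 0.031 and 0.175 with the block. Without the block the difference in ABCB1 between ABTr4 and the other clones did not pass.

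Translation termination was measured because its factors set how often ribosomes read through a stop codon. ETF1 (hg19 chromosome 5, 137841782 to 137878989), which encodes the release factor eRF1, fell from 253 ± 39.1 to 126 ± 22.2 CPM, a log2 fold change of -1.02 (SE 0.22, edgeR adjusted p = 0.016). Its edgeR adjusted p was 0.104 without PEO1 replicate 1 and 0.061 without PEO1 replicate 2. With the block the log2 fold change of ETF1 was -1.03 (SE 0.13, edgeR adjusted p = 3.3e-04). ETF1 lies among adjacent genes with a median log2 fold change of -0.85 in the clones. GSPT1, which encodes its partner eRF3a, had a log2 fold change of -0.07 (SE 0.34, edgeR adjusted p = 0.92). PABPC1, the poly(A) binding protein, fell from 4202 ± 859 to 1448 ± 264 CPM (log2 fold change -1.56, SE 0.22, edgeR adjusted p = 0.0029). Of 27 tested termination and readthrough genes, 3 fell and 1 rose, also when adjusted over the list alone, and with the block 11 fell and 1 rose. The list had a camera adjusted p of 0.082, and of 0.012 with the block, where the adjusted p = 0.78 with an estimated correlation. It also passed with fry (adjusted p = 0.015), without ABTr2 replicate 1 (camera adjusted p = 0.033), without ABTr3 replicate 2 (0.049) and without ABTr4 replicate 1 (0.025).

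The list of nonsense-mediated decay factors did not pass in the mean of the clones (camera adjusted p = 0.38). Of 22 tested, 1 fell, also when adjusted over the list alone, and 3 rose and 5 fell with the block. In ABTr1 and ABTr2 the list passed as lower without PEO1 replicate 2, and in each of them without its own replicate 1. UPF1, the central helicase of this pathway, had a log2 fold change of -0.28 (SE 0.30, edgeR adjusted p = 0.59) and SMG1, the kinase that phosphorylates it, one of -0.12 (SE 0.38, edgeR adjusted p = 0.86). The gene that fell was DCP2, a decapping enzyme, by 1.19 (SE 0.18, edgeR adjusted p = 0.0039) on the log2 scale, with an edgeR adjusted p of 0.054 without PEO1 replicate 2. DCP2 lies on chromosome 5 among adjacent genes with a median of -0.86. Of 19 tested transcripts that this pathway degrades, 3 fell and 0 rose, 4 fell when adjusted over the list alone, and 8 fell with the block. The camera adjusted p was 0.097, and 0.035 with the block, where the adjusted p = 0.78 with an estimated correlation. The list passed with fry (adjusted p = 0.042), and the camera adjusted p was 0.0487 without PEO1 replicate 1, 0.0487 without ABTr1 replicate 1 and 0.042 without ABTr2 replicate 1. GAS5, a noncoding host gene of small nucleolar RNAs, fell by 1.56 (SE 0.39, edgeR adjusted p = 0.028) on the log2 scale. Its value was -0.56 (edgeR adjusted p = 0.46) without PEO1 replicate 2, and the call also ended with limma-voom and without ABTr1 replicate 1, ABTr3 replicate 1 or ABTr3 replicate 2.

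Of 77 tested cytosolic ribosomal protein genes, 3 fell and 0 rose, 1 fell when adjusted over the list alone, and 46 fell and 1 rose with the block (camera adjusted p = 3.3e-04, and adjusted p = 0.97 with an estimated correlation). The median log2 fold change was -0.50. Without PEO1 replicate 2 the camera adjusted p was 0.082, and fry gave an adjusted p of 0.37 (0.020 with the block). RPL17 on chromosome 18, a protein of the large subunit, fell by 1.69 (SE 0.29, edgeR adjusted p = 0.0063) on the log2 scale, and its edgeR adjusted p was 0.057 without PEO1 replicate 2. RPL17 lies among adjacent genes with a median of -1.08, and ribosomal protein genes have many processed pseudogenes whose treatment in the counting was not given.

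The mitosis, DNA replication, p53 target, apoptosis and respiratory chain lists missed the threshold in this comparison with all libraries kept. Of 20 mitosis genes and 30 DNA replication genes 0 passed, also when adjusted over each list alone, and 1 rose and 1 fell, and 2 rose and 3 fell, with the block (camera adjusted p = 0.92 and 0.82). The mitosis list passed with opposite signs when a parental library was left out, higher without PEO1 replicate 1 (camera adjusted p = 0.048) and lower without PEO1 replicate 2 (camera adjusted p = 0.041). Of 21 p53 target genes, 2 fell and 1 rose, also when adjusted over the list alone, and 3 rose and 3 fell with the block (camera adjusted p = 0.82). Of 20 apoptosis regulators, 4 fell and 1 rose, 5 fell and 2 rose when adjusted over the list alone, and 5 fell and 3 rose with the block (camera adjusted p = 0.82). BID, a death-promoting BCL2 family gene, fell from 134 ± 1.15 to 60.2 ± 10.7 CPM (edgeR adjusted p = 0.0037) and passed in all 17 alternatives. Of 29 nuclear respiratory chain genes, 3 fell and 0 rose, 2 fell when adjusted over the list alone, and 11 fell and 1 rose with the block (camera adjusted p = 0.11). That list passed without PEO1 replicate 2 (camera adjusted p = 0.029), ABTr2 replicate 2 (0.040) or ABTr3 replicate 2 (0.036). ATP5A1, the alpha subunit of the mitochondrial ATP synthase on chromosome 18, fell from 638 ± 167 to 209 ± 18.1 CPM (edgeR adjusted p = 0.0015) and passed in all 17 alternatives.

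Of 14 hypoxia and glycolysis genes, 1 rose and 1 fell, also when adjusted over the list alone, and 2 rose and 1 fell with the block (camera adjusted p = 0.82). The gene that fell was EGLN3, an oxygen-sensing prolyl hydroxylase, from 19.3 ± 4.06 to 4.24 ± 1.93 CPM (edgeR adjusted p = 0.0027). Of 14 Wnt target genes, 2 fell and 1 rose, also when adjusted over the list alone, and 4 fell and 2 rose with the block (camera adjusted p = 0.82). The list's median (0.13) and mean (-0.07) differed in sign, and its test pointed down. RNF43, a ligase that removes Wnt receptors, fell from 4.22 ± 2.35 to 0.317 ± 0.182 CPM (edgeR adjusted p = 8.3e-04). Of 16 NRF2 antioxidant genes, 3 fell and 1 rose, 3 fell and 2 rose when adjusted over the list alone, and 4 fell and 3 rose with the block (camera adjusted p = 0.80). Of 11 NAD metabolism genes, 1 rose and 0 fell, 0 passed when adjusted over the list alone, and 6 rose and 1 fell with the block (camera adjusted p = 0.38). Of 11 stemness and aldehyde dehydrogenase genes, 1 fell, 0 passed when adjusted over the list alone, and 1 rose and 1 fell with the block (camera adjusted p = 0.82). Of 12 replication-dependent histone genes, 0 passed over all genes and when adjusted over the list alone, and 2 fell with the block (camera adjusted p = 0.38). In the 3 tested cancer-testis genes, 0 passed, 2 rose when adjusted over the list alone, and 2 rose with the block (camera adjusted p = 0.38). One of them, SSX1, had 0 parental reads and 355 clone reads, at least 25.4-fold higher in the clones.

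Marker lists of other cell types did not pass against other genes (camera adjusted p = 0.33 for fibroblasts, 0.24 for leukocytes and 0.38 for both endothelium and mesothelium). Against no change, the leukocyte and endothelial lists passed upward with fry (adjusted p = 0.0073 and 0.030), and the fibroblast and mesothelial lists did not (0.067 and 0.14). Of 5 tested fibroblast markers, 2 rose, 3 rose when adjusted over the list alone, and 3 rose and 1 fell with the block. Of 6 leukocyte markers, 2 rose, also when adjusted over the list alone, and 2 rose and 1 fell with the block. These were LAPTM5, a lysosomal membrane gene of blood cells with 0 parental and 863 clone reads, at least 61.7-fold higher in the clones, and CD68, another lysosomal gene, at 32.6 ± 2.06 CPM in parental cells and 98.1 ± 26.6 CPM in the clones. The edgeR adjusted p of CD68, 0.0065, rose above the threshold without PEO1 replicate 1 or PEO1 replicate 2, to 0.057 at the highest. The T cell and pan-leukocyte genes CD3D and PTPRC stood at 0 CPM and 0.0641 CPM in the clones. Of 8 endothelial markers, 1 rose and 1 fell, 2 rose and 1 fell when adjusted over the list alone, and 4 rose and 1 fell with the block. Of 5 mesothelial markers, 1 rose and 2 fell, also when adjusted over the list alone, and 2 rose and 2 fell with the block. UPK3B, a mesothelial and urothelial surface gene, fell by 3.63 (SE 0.32) on the log2 scale (edgeR adjusted p = 3.7e-04), and LRRN4 rose from 0.547 ± 0.664 to 10.4 ± 2.73 CPM (edgeR adjusted p = 0.011). The log2 fold change of LRRN4, 4.13, was 6.94 without PEO1 replicate 1.

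The comparisons clone by clone asked which changes each clone carried. CDH1 was at 252 CPM in parental cells and at 5.53, 1.15, 0.721 and 0.129 CPM in ABTr1, ABTr2, ABTr3 and ABTr4, and ZEB1 was at 2.46 CPM in parental cells and at 46.4, 41.1, 47.8 and 47.5 CPM in the clones (edgeR adjusted p at most 0.021 for CDH1 and at most 0.0013 for ZEB1). The ZEB1 calls held whichever library was left out. The CDH1 call ended without PEO1 replicate 2 or either ABTr1 library in ABTr1 (edgeR adjusted p up to 0.11), without ABTr2 replicate 1 in ABTr2 (0.058) and without either ABTr3 library in ABTr3 (up to 0.091). Of 2332 genes called in any clone, 690 passed with the same sign in each of the 4, 343 higher and 347 lower, and 665 of them when a change of at least 2-fold was asked for as well. With the replicate block there were 2088, 1066 higher and 1022 lower. Called with opposite signs in different clones were 0 of the 2332 by edgeR and 11 of 7021 with the block. In 20 simulations of unchanged clones against shared simulated controls the highest count was 0. With no changed gene hardly any could pass, so that value sets no baseline for the 690. Independent lists of the observed sizes would share 0.046 higher and 0.041 lower genes, which leaves out the shared controls. The median correlation of fold changes between clones was 0.902, against 0.503 in the simulations, and the median covariance was 2.03, against 0.181, a difference of 1.85. The simulated covariance reflects shared controls alone, in data with no replicate effect. Splitting the 2 parental libraries would leave 1 in each part, so how much the shared controls added to the count of 690 was not measured. Whether the 4 clones arose separately was not tested either, so these 690 genes need not have changed independently in each clone. The count of 690 was 162 without PEO1 replicate 2, 178 and 179 without ABTr1 replicates 1 and 2, 321 and 344 without ABTr2 replicates 1 and 2, 185 and 77 without ABTr3 replicates 1 and 2, and 336 and 321 without ABTr4 replicates 1 and 2. DESeq2 gave 1471.

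In ABTr1, 11 of 17 cholesterol synthesis genes fell, 13 when adjusted over the list alone, and 14 with the block (camera adjusted p = 4.3e-10, and adjusted p = 0.31 with an estimated correlation). HMGCS1, the synthase at the entry of the pathway, fell from 624 to 130 CPM (log2 fold change -2.26, SE 0.32, edgeR adjusted p = 0.0075, up to 0.070 without either ABTr1 library). Of 77 ribosomal protein genes 4 fell, 2 when adjusted over the list alone, and 62 with the block (camera adjusted p = 6.2e-10, adjusted p = 0.63 with an estimated correlation, and fry adjusted p = 0.22). Of 12 drug efflux genes 1 rose, 6 when adjusted over the list alone, and 9 with the block (camera adjusted p = 0.0034, and adjusted p = 0.21 with an estimated correlation). Of 27 translation termination genes 2 fell and 1 rose, also when adjusted over the list alone, and 13 fell and 1 rose with the block (camera adjusted p = 0.0018). Of 19 transcripts degraded by nonsense-mediated decay 1 fell, 0 when adjusted over the list alone, and 11 with the block (camera adjusted p = 0.0015). Both had an adjusted p = 0.21 with an estimated correlation. The tRNA synthetase, ATF4 and respiratory chain lists also passed as lower, with 3 of 20, 2 of 23 and 3 of 29 genes lower, 6, 13 and 5 when adjusted over the list alone, and 13, 15 and 12 with the block (camera adjusted p = 4.7e-04, 2.6e-05 and 4.2e-04, and adjusted p = 0.35, 0.45 and 0.51 with an estimated correlation). The ATF4 list had a camera adjusted p of 0.091 without PEO1 replicate 2. Serous lineage genes fell in 5 of 12 (1 higher), in 7 (1 higher) adjusted over the list alone and in 7 (2 higher) with the block, and estrogen response genes in 2 of 12 (1 higher), in 4 (1 higher) adjusted over the list alone and in 4 (1 higher) with the block (camera adjusted p = 5.8e-04 and 0.022, and adjusted p = 0.12 and 0.28 with an estimated correlation). The estrogen list had a camera adjusted p of 0.11 without PEO1 replicate 2 and 0.051 without ABTr1 replicate 2. NF-kB genes rose in 3 of 17, in 8 (1 lower) adjusted over the list alone and in 12 (1 lower) with the block (camera adjusted p = 3.3e-04, and adjusted p = 0.12 with an estimated correlation). Hypoxia and glycolysis genes rose in 2 of 14, in 5 (1 lower) adjusted over the list alone and in 6 (1 lower) with the block (camera adjusted p = 0.044, 0.054 with the block, and adjusted p = 0.51 with an estimated correlation), and this list missed the threshold without any one library other than ABTr1 replicate 2 (camera adjusted p up to 0.27). Epithelial genes fell in 17 of 23, in 21 adjusted over the list alone, and mesenchymal genes rose in 6 of 20, in 8 adjusted over the list alone and in 10 with the block (camera adjusted p = 4.0e-24 and 7.3e-10, and adjusted p = 0.12 for both with an estimated correlation). VIM reached 380 CPM, a log2 fold change of 7.80 (SE 0.73, edgeR adjusted p = 0.0031). Against parental, 1611 genes passed in ABTr1, 903 higher and 708 lower, and 4956 with the block, 2562 higher and 2394 lower. The count was 455 without PEO1 replicate 2, 221 and 238 without ABTr1 replicates 1 and 2, and 1048 and 1056 without ABTr3 replicates 1 and 2. DESeq2 called 3175 genes, and 699 passed when only ABTr1 and parental were fitted.

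In ABTr2, epithelial genes fell in 17 of 23 and in 22 adjusted over the list alone, with 23 lower with the block, and NF-kB genes rose in 5 of 17, in 12 (1 lower) adjusted over the list alone and in 13 (1 lower) with the block. Mesenchymal genes rose in 6 of 20, in 10 adjusted over the list alone and in 10 with the block. Serous lineage genes fell in 5 of 12 and rose in 1, and 7 fell and 1 rose when adjusted over the list alone. These 4 lists passed in ABTr2 (camera adjusted p = 3.9e-31, 2.8e-08, 6.1e-13 and 2.1e-05) and the adjusted p = 0.045 for each with an estimated correlation, which became 0.14 for each with the block. Drug efflux passed as higher, and ribosomal protein, tRNA synthetase, ATF4, estrogen and cholesterol lists as lower (camera adjusted p = 0.0096, 0.0074, 0.010, 2.1e-05, 0.037 and 0.0023). None of these passed with an estimated correlation. Drug efflux lost its call without ABTr2 replicate 2, and the others without PEO1 replicate 2. The ribosomal list also lost its call without ABTr2 replicate 1, and the tRNA synthetase and estrogen lists without ABTr2 replicate 2. MAOA was at its highest here, at 50.1 CPM (log2 fold change 7.56, edgeR adjusted p = 0.0033). The efflux pump gene ABCG2 was at 3.42 and 10.9 CPM in the 2 ABTr2 libraries and 1.04 and 1.24 CPM in the parental ones (log2 fold change 2.64, SE 0.65, edgeR adjusted p = 0.049). That call ended without any one library other than ABTr2 replicate 1, and without ABTr2 replicate 2 the log2 fold change was 1.57 (edgeR adjusted p = 0.24). In all 1008 genes passed, 545 higher and 463 lower, and 3640 with the block, 1861 higher and 1779 lower. The count was 251 without PEO1 replicate 2, 570 and 575 without ABTr1 replicates 1 and 2, 406 and 393 without ABTr2 replicates 1 and 2, and 643 and 634 without ABTr3 replicates 1 and 2. DESeq2 called 2488 genes, and 78 passed when only ABTr2 and parental were fitted.

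In ABTr3, the cytokine gene IL1B was at 241 CPM (log2 fold change 9.98, edgeR adjusted p = 0.0059, and 0.0505 without PEO1 replicate 2) and IL1A at 58.7 CPM (log2 fold change 6.59, edgeR adjusted p = 0.0024). NF-kB genes rose in 6 of 17, in 9 (1 lower) adjusted over the list alone and in 10 (1 lower) with the block (camera adjusted p = 1.3e-07, and adjusted p = 0.067 with an estimated correlation). Epithelial genes fell in 19 of 23 and in 23 adjusted over the list alone (camera adjusted p = 9.8e-34, and adjusted p = 0.067 with an estimated correlation), and mesenchymal genes rose in 7 of 20, in 8 adjusted over the list alone and in 8 (1 lower) with the block (camera adjusted p = 2.4e-07, and adjusted p = 0.10 with an estimated correlation). Ribosomal protein, tRNA synthetase, ATF4, serous lineage, estrogen and cholesterol lists also passed (camera adjusted p = 9.7e-06, 0.025, 5.2e-04, 1.6e-05, 0.025 and 1.5e-04), but none with an estimated correlation. The tRNA synthetase, ATF4 and estrogen lists lost their call without PEO1 replicate 2, and the ribosomal, tRNA synthetase and estrogen lists without ABTr3 replicate 1. In all 1216 genes passed, 574 higher and 642 lower, and 3722 with the block, 1810 higher and 1912 lower. The count was 301 without PEO1 replicate 2, 646 and 651 without ABTr1 replicates 1 and 2, and 203 and 81 without ABTr3 replicates 1 and 2. DESeq2 called 2526 genes, and 659 passed when only ABTr3 and parental were fitted.

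In ABTr4, epithelial genes were at their lowest levels of the 4 clones for CDH1 (0.129 CPM) and EPCAM (70.1 CPM), although ABTr4 did not differ from the other 3 clones in either (edgeR adjusted p = 0.76 and 0.68). Epithelial genes fell in 20 of 23 and in 23 adjusted over the list alone (camera adjusted p = 9.2e-38, and adjusted p = 0.068 with an estimated correlation). Estrogen response genes fell in 3 of 12 and rose in 1, fell in 7 and rose in 1 adjusted over the list alone, and fell in 7 and rose in 1 with the block (camera adjusted p = 0.0019, and adjusted p = 0.16 with an estimated correlation). ATF4, NF-kB, mesenchymal, serous lineage and cholesterol lists also passed (camera adjusted p = 3.0e-05, 8.4e-05, 1.7e-05, 2.2e-07 and 0.0041), but none with an estimated correlation. The ATF4 and cholesterol lists lost their call without PEO1 replicate 2. SHFM1, the small partner of BRCA2 on chromosome 7, fell from 112 to 44.1 CPM (log2 fold change -1.34, SE 0.22, edgeR adjusted p = 0.010, up to 0.078 without either ABTr4 library). In all 1602 genes passed, 736 higher and 866 lower, and 4450 with the block, 2159 higher and 2291 lower. The count was 578 without PEO1 replicate 2, 1006 and 1019 without ABTr1 replicates 1 and 2, and 478 and 453 without ABTr4 replicates 1 and 2. DESeq2 called 3118 genes, and 447 passed when only ABTr4 and parental were fitted.

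In the fit without the block few genes set 1 clone apart from the others, and more did with it except in ABTr2. On simulated data the test among clones without the block recovered 2%, 36% and 76% of genes changed 2-fold, 4-fold and 8-fold in ABTr1. The test of ABTr1 against the others recovered 10%, 78% and 94%, so small differences could be missed. In ABTr1, IPCEF1 (chromosome 6), a partner of a guanine exchange factor for ARF6, was at 38.8 CPM against 0.254, 0.290 and 0.142 CPM in ABTr2, ABTr3 and ABTr4 (log2 fold change 7.46 against the mean of the other clones, SE 0.50, edgeR adjusted p = 0.0031). SESN3 (chromosome 11), a sestrin that restrains mTORC1, was at 22.7 CPM against 1.57, 4.97 and 2.89 CPM (log2 fold change 3.01, SE 0.28, edgeR adjusted p = 0.019). They were the only genes called by edgeR for ABTr1 (1363 at an unadjusted p under 0.05), and with the block 489 passed, 375 higher and 114 lower. The count of 2 was 1 without either ABTr1 library or either ABTr2 library and 0 without either ABTr3 or either ABTr4 library. IPCEF1 kept its call without either ABTr1 or ABTr2 library and lost it without either ABTr3 or ABTr4 library, with an edgeR adjusted p of up to 0.074. SESN3 lost its call without any one of the 8 clone libraries and with the length correction, with an edgeR adjusted p of up to 0.29. For ABTr2, ABTr3 and ABTr4 against the other clones edgeR called 0 genes (495, 671 and 862 at an unadjusted p under 0.05), limma-voom 0 in each, and DESeq2 18, 75 and 158. With the block edgeR called 0, 34 and 90. Over all differences among the 4 clones edgeR called 1 gene, IPCEF1 (874 at an unadjusted p under 0.05). It called 0 without either PEO1 library, ABTr1 replicate 1 or any ABTr2, ABTr3 or ABTr4 library, and with the block it called 139. DESeq2 called 285 and limma-voom 0. For ABTr1 against the others DESeq2 called 192 genes and limma-voom 2. VIM, at 380 CPM in ABTr1 and 49.5 to 95.5 CPM in the other clones, did not differ by this test (edgeR adjusted p = 0.29), and did with the block (edgeR adjusted p = 0.013). ABCB1, which was lower in ABTr4, showed the same pattern, with an edgeR adjusted p of 0.24 against the other clones and 0.028 with the block.

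Genes on 3 chromosome arms shifted together in all 4 clones, a pattern looked for only after the fold changes had been seen. On chromosome 18, from 32.1 to 78.0 Mb, 95 genes had a median log2 fold change of -1.16, and 65 fell and 1 rose (77 and 3 with the block). ATP5A1, RPL17 and NARS lie there. On chromosome 5, from 58.3 to 156.9 Mb, 280 genes in 7 bins had a median of -0.74, and 113 fell and 5 rose (187 and 15 with the block). ETF1, DCP2 and RAD50 lie there. On chromosome 16, from 72.8 to 90.1 Mb, 96 genes had a median of 0.74, and 36 rose and 3 fell (66 and 5 with the block). SLC7A5, which fell, lies there. In 1000 shuffles of gene order over the 288 bins, bin medians ran from -0.59 to 0.63. On chromosome 7, from 75.96 to 116.87 Mb, 160 genes had a median of -0.70 in ABTr4 against the other clones, and ABCB1 and SHFM1 lie there. These bins were chosen for a median at or under -0.4 in that same comparison, which the shuffles did not cover. BRCA2 lies among genes with a median of 0.05.

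**Figure D4:**
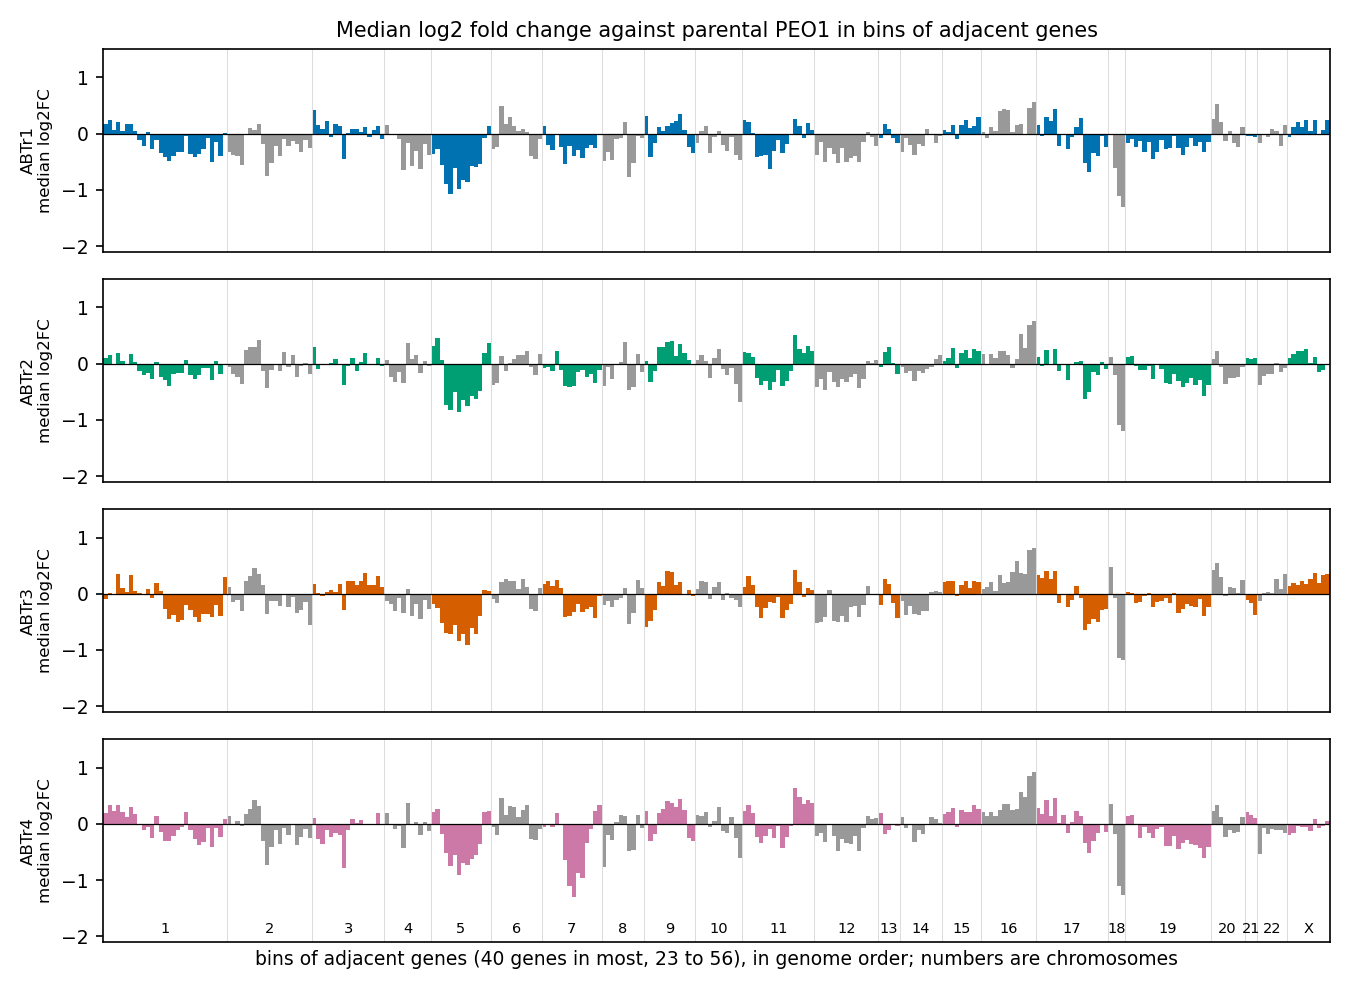
Median log2 fold change against parental of bins of adjacent genes (40 in most bins) along the chromosomes, for each clone. Bins on chromosomes 5 and 18 are lower and bins at the end of chromosome 16 are higher in all 4 clones, and bins on chromosome 7 are lower in ABTr4.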

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

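The genes below came from a comparison planned before the data were examined. Of the settings named in this part, the length correction was chosen after the results were seen. IPCEF1 stood apart in ABTr1, with a log2 fold change of 7.46 against the mean of the other 3 clones (SE 0.50, edgeR adjusted p = 0.0031). SESN3 did so too, with a log2 fold change of 3.01 (SE 0.28, edgeR adjusted p = 0.019). Neither call was firm. That of IPCEF1 ended without either ABTr3 or ABTr4 library (log2 fold change 6.13 to 8.14 with 1 library left out). That of SESN3 ended without any one clone library and with the length correction (2.57 to 3.34 with 1 library left out). No explanation was tested for either gene.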

How the results depend on the processing

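The length correction, and leaving out libraries for genes called in 1 clone, were chosen after the results were seen, and every setting fixed beforehand was run. Of 276 alternative counts 180 stayed within 1.5 times and 96 did not; of 1868 gene values 1666 were the same, 181 weaker, 11 stronger and 10 reversed. With the replicate block the counts were 5699 (mean), 4956, 3640, 3722 and 4450 (ABTr1 to ABTr4), 2088 (same way in all 4), 489, 34 and 90 (ABTr1, ABTr3 and ABTr4 against the others) and 139 (among clones), and with block and length correction 5999, 5315, 3833, 3950, 4649, 2223, 311, 36, 90 and 129. DESeq2 gave 4072, 3175, 2488, 2526, 3118 and 1471 for the same first 6, 192, 18, 75 and 158 for each clone against the others and 285 among clones. Without a filter ABTr1 and ABTr4 against the others gave 6 and 1 and the clones 2, limma-voom gave 0 among clones, and the length correction gave 1 for ABTr1 against the others. Only the compared groups gave 699, 78, 659 and 447 for ABTr1 to ABTr4. Shifted lists with an estimated correlation were 0, 0, 4, 0 and 0, and fry gave 5 in ABTr3. With 1 library left out the counts ran from 918 to 2527 (mean), 77 to 749 (same way), 221 to 1559 (ABTr1), 251 to 1028 (ABTr2), 81 to 1256 (ABTr3), 453 to 1594 (ABTr4), 0 to 2 (ABTr1 against the others) and 0 to 1 (among clones), and lists in ABTr2 from 8 to 20. Signs reversed for ABCB1 (0.32 with limma-voom, 1.67 with the clone as the unit) and, with 1 library left out, for ABCB1 (-0.66 to 0.31), GSPT1 (-0.28 to 0.14), UPF1 (-0.54 to 0.0039), SMG1 (-0.35 to 0.11) and PAX8 (-0.23 to 0.49), and none of these reversed values passed. The cause was not tested.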

Other observations

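The chromosome regions, the genes held out from choosing them, the length correction, the bootstrap intervals and the bounds used in this part were chosen only after the results had been seen.

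The fall of the epithelial genes could come from cells of another type, from gene dosage or from another cell line. Fibroblasts are argued against, since the most abundant fibroblast marker reached 8.92 CPM in the clones. Of the 23 tested epithelial genes, 34.8% lay in bins with a median at or under -0.4. That share met the set bound but exceeded that of every other list except mesothelial markers (40%), so it does not decide. Dosage is argued against as the main source, since 1 of the 23 lay in the regions lower in all 4 clones. The list's median fall was also larger than the medians of those regions (-1.16 and -0.74). Another line stays open: 4 genes at 5 CPM or more in the clones had at most 3 parental reads, under the bound of 20, but that bound was a poor one, as 46 genes were at 5 CPM or more in the clones and at most 0.5 CPM in parental cells and 46 the other way, and counts hold no genotype. A change of cell state under selection by the drug was not tested and remains possible.

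The shift of adjacent genes might reflect gene dosage, a few neighboring genes of a cell state or a length bias. When lower bins were chosen from every other gene, all lay on chromosome 18, and at least 87.2% of their genes not used to choose lay below the median of all such genes, which dosage needs, though DNA was not analysed here. With fewer genes per bin the lowest shuffled medians were -1.06 and -1.05. The chromosome 5 region, with a median of -0.74, could therefore hardly be chosen, and its absence says nothing about it. A few cell-state genes are argued against on chromosome 18 by a median of -1.13 or lower in the genes not used to choose. With the block and the length correction the medians were -1.18 on chromosome 18 and -0.80 on chromosome 5 (95% bootstrap interval -0.87 to -0.73), which argues against length bias as the whole cause there. On chromosome 16 the median was 0.74 with the block and 0.73 with the length correction added (interval 0.59 to 0.84). The interval reached into the range of shuffled bins, so the set test could not decide. The nearly unmoved median argues against length bias as the whole cause there. On chromosome 5, 84.3% of genes lay below the median of all genes, on chromosome 16 8.3%, and on chromosome 7 97.5% in ABTr4 against the other clones. The medians of these same genes chose the bins, so these shares cannot decide about a few cell-state genes. Dosage and a few cell-state genes stay open on chromosomes 5, 7 and 16, as does length bias on chromosome 7.

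Libraries with the same replicate number deviated together, which could come from gene length bias or sequencing depth. Reads of short genes took a larger share in replicate 2 of every group, such as 9.24% against 5.38% in ABTr4, so length bias may be a part of it. As the whole cause it is argued against, since the lowest correlation was 0.271 with the length trend removed and the length correction without the block gave 2916 genes. Depth is argued against, since the lowest correlation of deviations was 0.274 after thinning to equal depth. A shared day or batch of culture was not tested.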
